A study of Mus musculus with 16 samples.

How the data were processed

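Gene expression was measured by RNA sequencing in the mid section of the left ventricle of 16 C57Bl/6J mice aged 24 months, 8 with a history of more than 3 pregnancies (multiparous) and 8 virgin. Per the labels' protocols, hearts were flushed with cold saline before removal, RNA was isolated on silica columns, and libraries were made with a stranded total RNA kit that removes ribosomal RNA. They were sequenced as paired reads of 150 bases. Per the submitters' processing notes, the tools were bcl2fastq 2.20, Trim Galore 0.6.10, cutadapt 4.8, FastQC 0.12.1, STAR 2.7.11b, SAMtools 1.19.2 and HTSeq 0.11.1, with the mouse genome build GRCm38.p6. The annotation release and the strand setting of the counting are not given in the sources used here.

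The authors deposited 1 table of raw counts per library, with 55487 genes each. Reads assigned to no gene, between 26.5% and 33.1% of the total per library, stayed out of library sizes and tests. Genes were matched by identifier to the GENCODE M21 annotation of GRCm38, and 99.53% had an entry. Coordinates are from that annotation. The gene count per library ranged from 34560606 to 58890976 in 15 libraries and was 228325238 in virgin 8. A count of 0 allows a level of up to 3 counts, between 0.0131 and 0.0868 CPM by library. These floors cover counting error only, since the sources used here name no molecular identifiers, while intervals of fold changes include the spread between libraries.

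Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, genes kept by filterByExpr, a quasi-likelihood F-test on group alone, and Benjamini-Hochberg adjustment over 17813 genes at a threshold of 0.05. The version's default method was used. CPM values are scaled by TMM, and values in the text are mean ± SD of 8 libraries per group. Log2 fold changes are multiparous minus virgin, with SE from the F statistic and 95% intervals. Tested on simulated data with 200 changed genes, this fit called 52.2% of genes changed by 1.5-fold, 86.6% of those changed 2-fold and 97.0% of those changed 3-fold, and called 9 of 17613 unchanged genes. The simulated genes varied independently, without the tissue transcripts and unusual libraries described below. These rates may therefore not hold for the real comparison.

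Before the data were examined, 56 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule takes the 8 higher and 8 lower genes with the smallest p, the 6 higher and 6 lower with the largest change among genes past the threshold at a mean of at least 1 CPM, up to 4 members of each list called, and 10 genes named in advance. Predicted genes with no proper symbol were passed over. Where fewer than 10 genes passed, the genes with the smallest p are named as not having passed. The 52 lists with at least 5 tested members were compared with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with an estimated correlation and with fry beside it. The lists of mitochondrially encoded genes, lung and thyroid or thymus markers, replication-dependent histones and sex chromosome genes had 0, 2, 4 and 2 tested members and were not tested.

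Library measures and list means were compared by exact two-sided permutation over all 12870 assignments, adjusted over 60 measures. Lists of kidney, liver and brain genes were written after the main result was seen, and the 5 sums taken from them were adjusted among themselves and, beside that, over all 65 measures. A family of 12, the library measures and 4 tissue sums, had been used first. Its adjusted p is given only for the kidney genes not looked at before. One of the tissue lists holds these 28 kidney genes, whose values had not been looked at. Its 18 genes with a mean under 1 CPM were taken as a further version after the sum of all 28 was seen. That mean was taken over all 16 libraries, those rich in kidney transcripts included. The library names of the multiparous hearts carry 2 codes, P (4 libraries) and MP (4 libraries), whose meaning the labels do not give. These were compared with the same edgeR test. All virgin libraries carry a code of their own, AA. In the multiparous against virgin comparison, parity therefore cannot be told apart from a difference tied to the library codes. Alternatives included DESeq2 1.42.0, limma voom, other factors, filters and thresholds, a replicate block, a surrogate variable from sva 3.50.0, each code alone against the virgin hearts, and leaving out each library. No pair of libraries within a group agreed within sampling noise: over the 56 pairs, the lowest chi-square per degree of freedom was 9.79. The labels do not say that each library is a separate animal beyond the counts of mice, so p-values measure the spread between these libraries.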

Results

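Left ventricles of 8 multiparous and 8 virgin mice aged 24 months were compared to ask what past pregnancies leave in the heart's transcripts. The 16 libraries held 34560606 to 58890976 gene counts in 15 cases and 228325238 in virgin 8. In all, 17813 genes were tested.

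Of these genes, 1 was higher and 1 lower in multiparous hearts at an adjusted p under 0.05. Plekhh1, which encodes a protein with pleckstrin homology and FERM domains, measured 3.28 ± 0.37 CPM in multiparous against 1.72 ± 0.49 CPM in virgin hearts (SD, n = 8 each, edgeR adjusted p = 0.0446). Its log2 fold change was 0.94 (SE 0.15, 95% interval 0.63 to 1.25), and the lowest multiparous library, 2.84 CPM, lay above the highest virgin one, 2.62 CPM. Ankrd23, an ankyrin repeat protein of the muscle stretch-response family, measured 106.3 ± 15.1 CPM against 166.8 ± 27.6 CPM (edgeR adjusted p = 0.0446). It fell by 0.65 on the log2 scale (SE 0.10), and all 8 multiparous libraries lay below the virgin mean. Plekhh1 (ENSMUSG00000060716.7) lies on chromosome 12 at 79029163 to 79081655, plus strand, and Ankrd23 (ENSMUSG00000067653.12) on chromosome 1 at 36530188 to 36536883, minus strand, in GRCm38. Both counts are uncertain where genes overlap: 992 of the 6718 exonic bases of Plekhh1 lie opposite Pigh, and 2109 of the 2697 exonic bases of Ankrd23 are shared on the same strand with Gm42417, which averaged 0.039 CPM.

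At an unadjusted p under 0.05 stood 1447 genes, 719 higher and 728 lower, where 891 are expected by chance. Each call was lost in most fits that left out 1 library: Plekhh1 passed in 5 of 16 and Ankrd23 in 7 of 16, and the number of genes called ranged from 0 to 55 (without virgin replicate 7). DESeq2 called 130 genes, 62 higher and 68 lower, and limma voom called 3.

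The other higher genes with the smallest p did not pass. Cep128, a centrosomal protein, measured 19.9 ± 3.0 CPM in multiparous and 12.8 ± 2.3 CPM in virgin hearts (log2 fold change 0.64, SE 0.10, edgeR adjusted p = 0.0544). Irx5, a homeobox factor that patterns ventricular repolarisation, measured 15.4 against 9.10 CPM, and Cacna1h, a T-type calcium channel, 16.2 against 11.7 CPM. Arc measured 3.92 against 2.67 CPM and Thsd4, a matrix microfibril protein, 9.61 against 7.59 CPM. The proprotein convertase Pcsk6 measured 94.1 against 75.0 CPM, and Clec3b (tetranectin) 24.8 against 19.2 CPM. The edgeR adjusted p of these 6 genes ranged from 0.0745 for Cacna1h to 0.0954 for Pcsk6 and Clec3b.

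**Figure D1:**
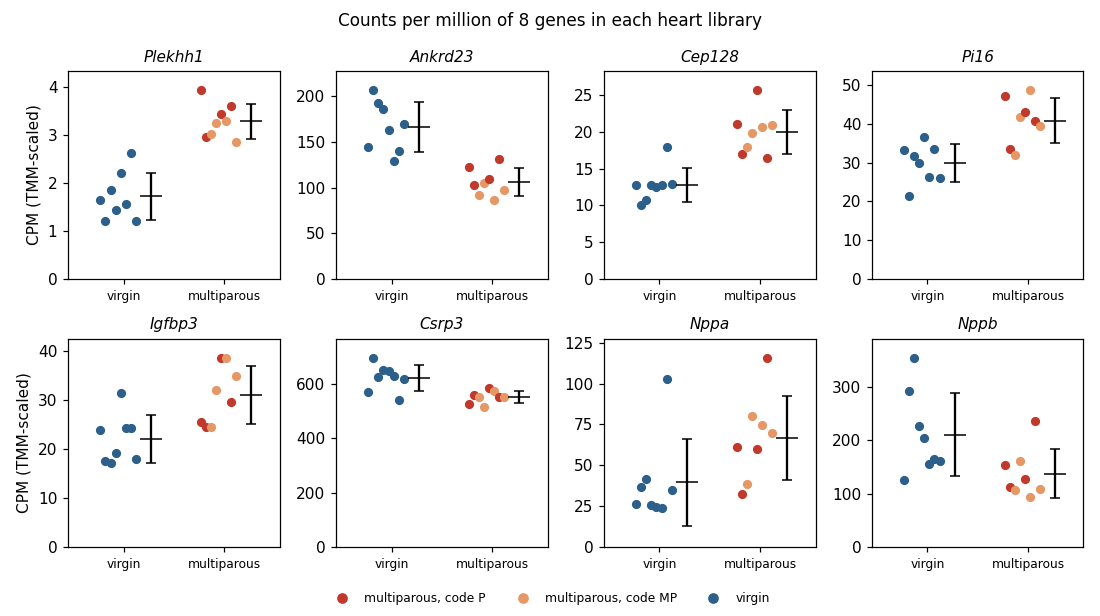
CPM (TMM-scaled, vertical axes from 0) of 8 genes in each of the 16 libraries; each point is 1 heart, coloured by library code, and the black mark is the mean with its SD. Plekhh1 shows no overlap between the groups, with 2.84 CPM as the lowest multiparous and 2.62 CPM as the highest virgin value.

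Most of the lower genes with the smallest p were genes of kidney tubules, and none of them passed. Kap, an androgen-regulated kidney protein, measured 0.772 ± 0.811 CPM in multiparous and 8.40 ± 5.47 CPM in virgin hearts (edgeR adjusted p = 0.0745). Cltrn (0.0921 against 1.31 CPM), the anion transporter Slc22a8 (0.0877 against 0.819 CPM), and the amino acid transporter genes Slc7a12 (0.104 against 1.43 CPM) and Slc3a1 (0.303 against 1.96 CPM) had the same adjusted p of 0.0745. Kcnj15, a potassium channel (1.71 against 3.39 CPM), and the splicing factor Srsf3 (65.0 against 73.9 CPM), whose groups did not overlap, completed the 8. Of the 30 lower genes with an adjusted p under 0.1, 16 were in the kidney list written after this was seen. Summed over its 31 genes, that list held 2.17 to 27.7 CPM in the multiparous and 8.02 to 181 CPM in the virgin libraries, and the difference in log2 sum was −2.78 (exact permutation p = 0.00218, adjusted p = 0.0109 over 5 tissue sums and 0.0707 over all 65 measures), a p that restates the observation since the genes were picked for it. Of 28 other kidney genes not looked at before, 10 averaged at least 1 CPM in these hearts. Their sum had a lower mean (log2 difference −0.18, exact permutation p = 0.0166, adjusted p = 0.0416 over 5, 0.36 over 65 and 0.0998 over the 12 measures first used), but the 18 below 1 CPM, taken after that sum was seen, gave −0.83 (exact permutation p = 0.111, adjusted p = 0.167).

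**Figure D2:**
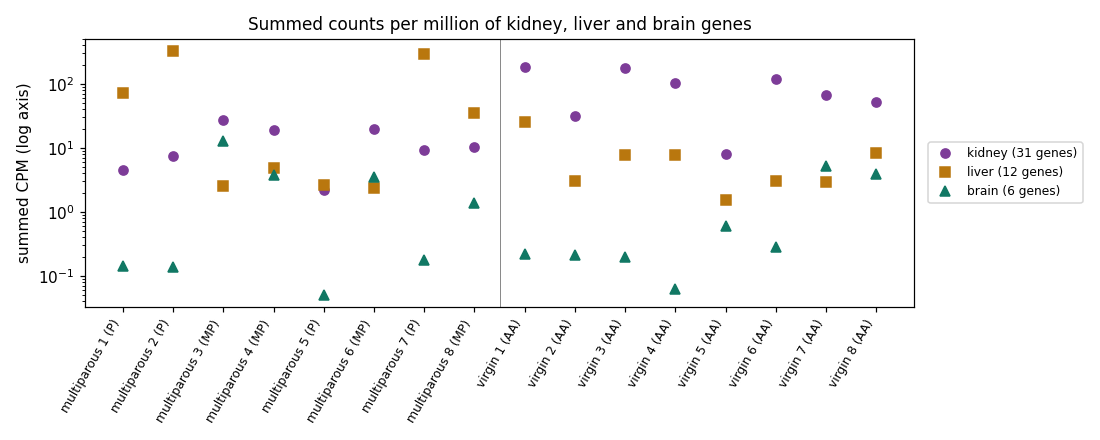
Summed CPM (log axis) of 31 kidney, 12 liver and 6 brain genes in each library, named by group, replicate and library code. Kidney sums reach 181 CPM in virgin 1, and liver sums reach 325 CPM in multiparous 2.

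With a preset correlation, 16 of 52 gene lists passed, 8 higher and 8 lower in multiparous hearts. None passed with an estimated correlation, where their adjusted p ranged from 0.665 to 0.804, nor with fry (lowest adjusted p 0.473 directional, 0.0841 mixed).

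Fibroblast markers were among the higher lists (camera adjusted p = 6.73e-05, adjusted p = 0.665 with an estimated correlation): 17 of 23 members had higher and 6 lower means in multiparous hearts. No member passed over all genes, while 7 higher and 1 lower passed adjusted over the list alone. Pi16, of adventitial fibroblasts, measured 40.8 ± 5.9 against 29.8 ± 4.9 CPM. Fbln1 (fibulin 1) measured 110 against 80.7 CPM, the actin-severing protein Gsn 1013 against 781 CPM and the ferritin receptor Scara5 26.3 against 19.2 CPM. Fibrillar collagens did not go with these genes. Col1a1, itself a member of the fibroblast list, measured 92.2 ± 15.6 against 101.6 ± 18.3 CPM, and Col3a1 175 ± 34 against 187 ± 43 CPM. The collagen and matrix list, which shares members with the fibroblast list, had a median log2 fold change of −0.04 (camera adjusted p = 0.239). Smooth muscle and pericyte markers had a median of −0.08 (camera adjusted p = 0.291) and endothelial markers of 0.01 (camera adjusted p = 0.673).

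Endocardial markers (camera adjusted p = 6.73e-05, adjusted p = 0.665 with an estimated correlation) had all 10 members higher, with a median log2 fold change of 0.24. Smoc1 measured 6.04 ± 1.69 against 3.41 ± 2.26 CPM, Plvap, of the endothelial diaphragm, 13.97 against 8.74 CPM, Tmem108 5.41 against 3.58 CPM and the junction protein Cgnl1 51.5 against 44.4 CPM. With kidney, liver and brain covariates the log2 fold changes of Plvap, Tmem108 and Cgnl1 turned to −0.0095, −0.26 and −0.0028. The kidney sum was itself lower in multiparous hearts, so this fit cannot fully tell it from parity. The complement list (camera adjusted p = 0.000148, adjusted p = 0.665 with an estimated correlation) had 16 of 18 members higher. Its mean was higher than in virgin hearts by 0.43 in the MP-coded libraries (exact permutation p = 0.0505) and by 0.09 in the P-coded ones (exact permutation p = 0.552). The central component C3 measured 477 ± 213 against 316 ± 51 CPM, with the highest value in multiparous 6 (978 CPM). Cd55 measured 14.9 against 12.2 CPM and C1ra 22.8 against 18.8 CPM. In neither list did a member pass, over all genes or adjusted over the list alone.

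Genes of the respiratory chain and of glucose use had small differences in 1 direction, while fatty acid oxidation genes did not share it (15 of 25 higher, median log2 fold change 0.01, camera adjusted p = 0.371). Of the nuclear genes of respiratory complexes II to V, 40 of 41 had lower means in multiparous hearts (median log2 fold change −0.06, camera adjusted p = 1.24e-05, adjusted p = 0.685 with an estimated correlation), and of complex I 35 of 37 (median −0.07, camera adjusted p = 1.24e-05, adjusted p = 0.685 with an estimated correlation). No member of either passed over all genes or adjusted over the list alone. The direction of a still smaller difference turned with the scaling of the libraries: without factors, the log2 fold change of Myh6 went from −0.023 to 0.013. The respiratory chain genes named next, taken for their small p, kept their direction in all 36 alternatives, the one without factors included. The energy and sarcomere lists were not rerun without factors. Uqcrc2 of complex III measured 705 ± 48 against 772 ± 50 CPM, Atp5b of the ATP synthase 3957 against 4254 CPM, Atp5l 218 against 235 CPM and Cox7b 395 against 419 CPM. In complex I, Ndufa10 measured 507 against 555 CPM, Ndufa9 276 against 298 CPM, Ndufs6 155 against 166 CPM and Ndufb9 246 against 267 CPM. All 16 members of the tricarboxylic acid cycle list were lower (camera adjusted p = 0.000148, adjusted p = 0.667 with an estimated correlation), among them Idh3b (455 against 493 CPM), Sucla2 (372 against 408 CPM), Got2 (889 against 959 CPM) and Sdhb (435 against 464 CPM). In the glycolysis list 26 of 29 were lower (camera adjusted p = 0.000184, adjusted p = 0.665 with an estimated correlation), with Gapdh at 2461 ± 115 against 2767 ± 189 CPM, Pdhb at 461 against 511 CPM and Mpc1, of the pyruvate carrier, at 145 against 159 CPM. Branched-chain amino acid breakdown genes were lower in 17 of 18 (camera adjusted p = 0.00458, adjusted p = 0.761 with an estimated correlation), with Hibadh at 217 against 236 CPM and Hibch at 68.1 against 73.9 CPM, and did not pass without virgin replicate 2 (camera adjusted p = 0.051). No library gave a count on any of the 37 mitochondrial genes of the annotation, so the mitochondrially encoded part of these complexes was not measured under its own names. Nuclear copies identical to mitochondrial genes did not differ past the threshold, among them Gm28437, a copy of mt-Co3 (log2 fold change −0.09, edgeR adjusted p = 0.817).

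Sarcomere genes were lower in 20 of 24 (camera adjusted p = 0.000602, adjusted p = 0.665 with an estimated correlation), and 1, Csrp3, passed adjusted over the list alone. Csrp3, a Z-disc protein, measured 552 ± 23 against 623 ± 48 CPM. Tnnc1 (cardiac troponin C) measured 1460 against 1619 CPM, Myom1 1848 against 2054 CPM and Myoz2 685 against 742 CPM. The fetal gene and wall stress list was lower in 14 of 17 (camera adjusted p = 0.00127, adjusted p = 0.665 with an estimated correlation), and 4 members passed adjusted over the list alone, all lower. These were Csrp3, the calcineurin regulator Rcan1 (74.9 ± 11.1 against 97.2 ± 19.0 CPM), the small heat shock protein Hspb7 (1719 ± 148 against 1956 ± 109 CPM) and Nppb, the B-type natriuretic peptide (138 ± 46 against 211 ± 78 CPM). Nppa, the atrial natriuretic peptide, went the other way at 66.6 ± 26.0 against 39.6 ± 26.5 CPM (edgeR adjusted p = 0.511).

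**Figure D3:**
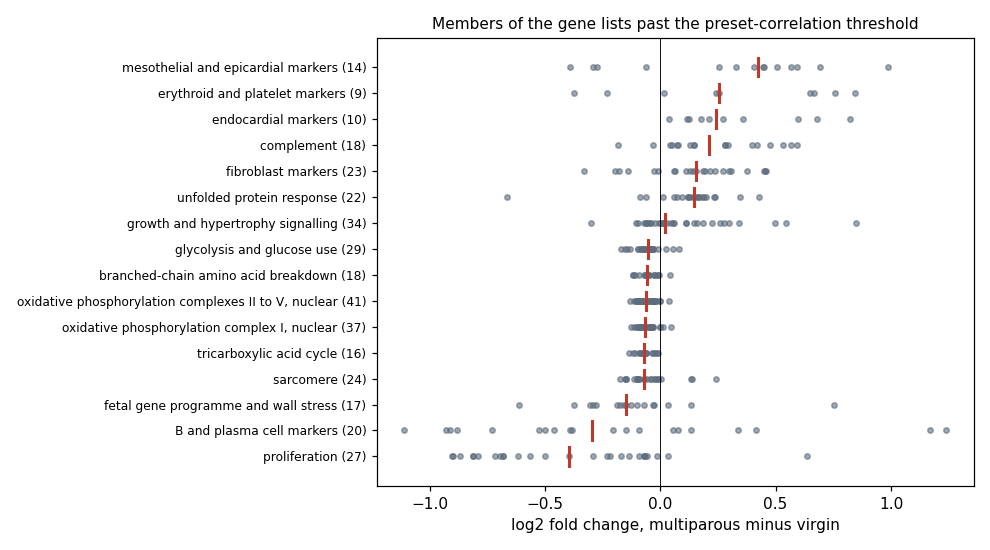
Log2 fold change (horizontal axis, multiparous minus virgin) of each tested member of the 16 lists past the preset-correlation threshold; points are genes, red bars are list medians, and the number tested is in brackets. Most members of the energy lists lie in a narrow band below 0 and a few above it, with medians of −0.06 and −0.07 for the respiratory complexes.

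Growth and hypertrophy signalling genes were higher in 23 of 34 (camera adjusted p = 0.0153, adjusted p = 0.665 with an estimated correlation), with a median log2 fold change of 0.02 and a mean of 0.10. The list did not pass without virgin replicate 1 (camera adjusted p = 0.107). Igfbp3, a carrier of insulin-like growth factors, measured 31.01 ± 6.0 against 21.99 ± 4.9 CPM and was the 1 member past the threshold adjusted over the list alone. The endothelin receptor Ednrb measured 27.6 against 22.5 CPM, Foxo3 188 against 168 CPM and Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, 283 against 242 CPM. The mean log2 CPM of the list was 5.52 ± 0.05 in multiparous and 5.42 ± 0.05 in virgin hearts (SD, n = 8 each, exact permutation p = 0.000932, adjusted p = 0.0559 over 60 measures), and it was the measure with the smallest p. Adjusted over the 52 list means alone, the value was 0.0485, so the family decides on which side of 0.05 it falls.

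Unfolded protein response genes were higher in 19 of 22 (camera adjusted p = 0.000602, adjusted p = 0.667 with an estimated correlation), with Herpud1 at 165 against 140 CPM, Manf at 44.9 against 33.4 CPM and Xbp1 at 64.3 against 58.5 CPM, while Atf3 measured 2.64 against 4.21 CPM. With kidney, liver and brain covariates the log2 fold change of Atf3 turned to 0.013. The mean of this list was higher by 0.205 in the MP-coded libraries (exact permutation p = 0.0465, adjusted p = 0.471) and differed by −0.00232 in the P-coded ones (exact permutation p = 0.974). Proliferation genes were lower in 25 of 27 (camera adjusted p = 0.0335, adjusted p = 0.804 with an estimated correlation). Aurkb measured 0.454 against 0.860 CPM, Ccnb2 0.555 against 1.03 CPM and Kif11 1.84 against 2.99 CPM, and Cenpf 55.5 against 35.7 CPM. Aurkb, Ccnb2 and Kif11 turned higher with a kidney covariate (log2 fold change 0.38, 0.39 and 0.27). The kidney sum in this fit, and in that of Atf3, was itself lower in multiparous hearts. The proliferation list passed in 9 of 16 fits that left out 1 library, and not without virgin replicate 1 (camera adjusted p = 0.907).

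In the B and plasma cell list (camera adjusted p = 0.0155, adjusted p = 0.804 with an estimated correlation) the test gave higher while the median log2 fold change was −0.29 and the mean −0.19. Ighm (28.9 ± 16.2 against 12.2 ± 6.3 CPM) and Ighd (1.45 against 0.647 CPM), immunoglobulin heavy chains of naive B cells, passed adjusted over the list alone, while Mzb1 measured 0.917 against 1.21 CPM. The virgin mean of Iglc2 (1.203 against 0.560 CPM) was carried by virgin 1 at 8.17 CPM, and its log2 fold change turned from −1.11 to 1.30 without virgin replicate 1. The list passed in 11 of 16 fits that left out 1 library (highest adjusted p 0.093). Mesothelial markers were higher in 10 of 14 (camera adjusted p = 0.0169, adjusted p = 0.761 with an estimated correlation), with Efemp1 at 12.7 against 9.64 CPM, Muc16 at 7.87 against 4.01 CPM and Gpm6a at 5.38 against 4.27 CPM. Its list mean was higher than in virgin hearts by 0.92 in the MP-coded libraries (exact permutation p = 0.0606) and differed by −0.12 in the P-coded ones (exact permutation p = 0.796), and it passed in 10 of 16 fits that left out 1 library (highest adjusted p 0.116). Erythroid and platelet markers were higher in 7 of 9 (camera adjusted p = 0.0335, adjusted p = 0.761 with an estimated correlation), with Hbb-bs at 7.18 ± 6.89 against 4.01 ± 3.03 CPM, Alas2 at 24.0 against 14.3 CPM and Bpgm at 20.4 against 17.1 CPM, and passed in 8 of 16 such fits (highest adjusted p 0.196).

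Among genes named in advance, the myosin heavy chains Myh6 (20360 ± 1220 against 20690 ± 1817 CPM) and Myh7 (231 ± 104 against 211 ± 110 CPM) and the calcium pump Atp2a2 (17000 ± 1139 against 17100 ± 1113 CPM) differed by less than the spread between hearts. The same held for Postn (43.9 ± 11.5 against 50.3 ± 14 CPM), the pyruvate dehydrogenase kinase Pdk4 (271 ± 91 against 259 ± 49 CPM) and the oestrogen receptor Esr1 (2.44 ± 0.47 against 2.24 ± 0.59 CPM). Their edgeR adjusted p ranged from 0.819 for Postn to 0.989 for Atp2a2. The direction of Myh6 and Atp2a2 turned when library totals were used without factors.

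Within the multiparous group, 22 genes differed between the MP-coded and P-coded libraries, 18 higher and 4 lower in MP. Zbtb16, a glucocorticoid-induced zinc finger factor, measured 158 ± 6 CPM in MP and 69.0 ± 9.8 CPM in P hearts (SD, n = 4 each, edgeR adjusted p = 0.000578). Lcn2, an iron-binding acute-phase protein, measured 4.84 against 1.31 CPM (edgeR adjusted p = 0.000896), the metallothioneins Mt2 9.52 against 3.94 CPM (edgeR adjusted p = 0.0021) and Mt1 88.1 against 59.4 CPM (edgeR adjusted p = 0.0102), and Fkbp5, a co-chaperone of the glucocorticoid receptor, 26.7 against 14.4 CPM (edgeR adjusted p = 0.0366). Virgin means lay between, at 86.9 CPM for Zbtb16 and 19.6 CPM for Fkbp5. Of the 16 glucocorticoid targets, 6 were higher over all genes tested and 8 adjusted over the list alone (camera adjusted p = 8.17e-08, adjusted p = 0.619 with an estimated correlation). Of 52 lists, 13 passed with a preset correlation and 0 with an estimated one. The means of 6 lists parted the codes, each with an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.286. These were glucocorticoid targets, nuclear and RNA quality transcripts (mean log2 CPM 6.36 in MP and 6.00 in P), macrophage markers (2.83 and 2.44), antioxidant, and autophagy and lysosome genes, all higher in MP, and cholesterol synthesis genes, lower in MP. Of the 11 tested nuclear and RNA quality genes, 1 passed over all genes, Snhg11 (4.33 in MP against 0.922 CPM in P). The median log2 fold change of that list was 0.164. The MP-coded libraries also held the higher sums of brain genes, and whether Snhg11 came with those was not tested. The kidney genes Kap (1.47 against 0.0994 CPM), Slc34a1 and Umod and the neuronal gene Grin2b (1.63 against 0.013 CPM) were also higher in MP. The number of genes ranged from 3 (without multiparous replicate 1 or 7) to 197 (without multiparous replicate 5), where 49 were higher and 148 lower in MP.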

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

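The tests of kidney, liver and brain genes, of cell markers, of gene length and GC content, and of nuclear copies were chosen only after the results they measure were seen, and the counts over other splits were planned.

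Among the 8 multiparous hearts, 22 genes differed between the libraries coded MP and P, among them the glucocorticoid-induced genes Zbtb16 and Fkbp5 and the metallothioneins Mt1 and Mt2. Of the 35 splits of these libraries into 4 and 4, 2 gave as many genes, the real one included, so chance is not excluded at 0.05. The other was replicates 1, 2, 7 and 8 against the rest, with 53 genes. Those are the 4 multiparous libraries with liver transcripts (72.3, 325, 293 and 35.6 CPM summed over 12 liver genes, against at most 4.91 CPM in the other 4), so that split follows a structure of the samples. Between multiparous and virgin hearts, 3 of 100 splits gave at least the 2 genes changed, the real one included. The highest other split gave 14 genes. It kept 7 virgin libraries in 1 group, so it holds most of the real contrast and is no clean measure of chance. The share of 3 in 100 is under 0.05, but it rests on 100 drawn splits and a count of 2 genes. Chance is therefore not firmly excluded for that count. For the lists chance is not excluded either: 52 of 100 splits gave as many as the real 16, and the highest gave 28. At an unadjusted p under 0.05, 14 of 100 splits gave at least the 1447 genes. The highest, 3272, came from the same split with 7 virgin libraries in 1 group.

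Kidney tubule genes such as Kap, Slc34a1, Umod and Miox had lower means in multiparous hearts. RNA from kidney in some libraries is a candidate explanation. Across the 8 virgin hearts, where parity is the same, the 27 tested kidney genes rose and fell together. Their median pairwise Spearman rho was 0.857, against 0.143 at the 95th percentile of 10000 gene sets matched on level. These genes were picked from these same data, and the matched sets were not picked as genes of 1 tissue. The rho therefore cannot decide whether RNA from kidney is the cause. For the 18 other kidney genes under 1 CPM the exact permutation p was 0.111, which decides nothing, since a limit on the mean over all libraries removes the genes that such RNA would raise most. Parity alone does not account for the spread of these genes: at the same parity, kidney sums ran from 8.02 CPM in virgin 5 to 181 CPM in virgin 1. Across the 8 multiparous libraries the same rho was 0.659. Whether parity is the whole cause of the difference between the groups stays open. The kidney sums of the MP and P codes (log2 CPM 4.18 and 2.35) gave an exact permutation p of 0.0286, the smallest that 4 against 4 can give. Adjusted over the 5 tissue sums it was 0.0714, and the number of pregnancies behind each code is not given.

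Fibroblast and endocardial markers lay higher, and genes of the respiratory chain, the tricarboxylic acid cycle and glucose use lower, in multiparous hearts. A lower share of heart muscle cells as the whole cause would raise markers of all other cell types alike. The fibroblast score less the smooth muscle and pericyte score was 0.27 in multiparous and 0.05 in virgin hearts (exact permutation p = 0.0131). Against endothelial markers the difference did not pass (exact permutation p = 0.168). These contrasts cannot decide the question, since the fibroblast list was taken for them because it was higher. The smooth muscle list also shares Des with the sarcomere list. For gene length and GC content, the score of the 78 respiratory chain genes less that of genes matched on length, GC and level differed by −0.04 (exact permutation p = 0.0909), so this stays open for the energy genes, and the other lists were not tested for it. A lower share of heart muscle cells, more fibroblast transcripts, and chance, which the splits do not exclude, all stay open. An effect of parity is untested beyond the comparison itself, in which it cannot be told apart from the library codes.

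The 37 mitochondrial genes had no count in any library, although heart muscle is rich in their transcripts. Mitochondrial reads counted on nuclear copies is a candidate explanation. Together, 9 copies that differ from the mitochondrial gene by over 1% of bases held 8.87% of counts on average. Of these, Gm13340, a copy of mt-Co1, alone held 7.88%, while Gm50174 held 0.000508%. No single one of 13500 other pseudogenes held more than 0.0118%. All 16 copies held between 17.9% and 21.3%. No biological explanation was tested.

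Single libraries stood far from the other 7 of their group in 21 of 220 groups of values tested. Chance gives about 5% per group for normally spread values. The groups were not independent, since list means stood beside their own members, so the count cannot be read as an excess. Virgin 8 had 228 M gene counts (M, mega), against 50.9 M in the next. In virgin 1 the share of reads outside genes was 12.2%, the B and plasma cell list mean was 3.21 (next 0.238), and log2 CPM was 4.76 for Ighm, 3.04 for Iglc2, 6.36 for Srsf3, 8.48 for Sucla2, 8.77 for Pdhb and 5.96 for Hibch. In virgin 7 log2 CPM was 6.69 for Nppa, 4.16 for Cep128, 4.02 for Cacna1h and 5.02 for Ednrb. In virgin 6 it was 7.33 for Herpud1, 8.30 for Pik3r1 and 4.79 for Bpgm, and in virgin 5 −4.07 for Slc7a12. Multiparous 6 had a complement list mean of 5.10, with C3 at 9.93 and C1ra at 5.23, and multiparous 7 had Ednrb at 4.54.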

How the results depend on the processing

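Chosen only after the data were seen were the fits with tissue covariates, without tissue genes or nuclear copies, with virgin 8 thinned, with the other edgeR method, with DESeq2 without the low-count filter, the lists without virgin 1 and with a surrogate variable, and each MP against P fit without a library.

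Plekhh1 stayed higher and Ankrd23 lower in all 36 alternatives (log2 fold change 0.76 to 1.15 and −0.80 to −0.52), but they passed in only 19 and 20 of them. Against 2 genes changed, 39 passed at an adjusted p under 0.1 and 0 at 0.01. DESeq2 gave 130, DESeq2 without the low-count filter 250, voom with quality weights 32 (17 higher, 15 lower), no filter beyond 1 count 56 (5 higher, 51 lower), and the replicate block 33 (7 higher, 26 lower). The labels state no pairing by replicate number. Of 8 pairs with the same number, 1 correlated above 0.1 (0.291), and 4 of 16 libraries correlated best with their own number. Whether hearts of the same number share a structure stays open. P-coded libraries alone gave 97 and MP-coded alone 0, with 4 multiparous hearts in each. The mean of the nuclear and RNA quality list differed by −0.27 between P-coded and virgin libraries (exact permutation p = 0.00808, adjusted p = 0.242) and by 0.09 for MP-coded ones (exact permutation p = 0.299). Total counts without factors, the test against a 1.2-fold change, 1 surrogate variable, the kidney covariate, and the 3 tissue covariates each gave 0 against these 2. At an unadjusted p under 0.05, edgeR without any such change gave 1447. The stricter p and the 1.2-fold test lower the count by construction. For the others the cause was not tested. Among them, the fits with a kidney covariate can lose calls because the kidney sum was itself lower in multiparous hearts (log2 difference −2.78).

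Leaving out 1 library gave 0 (without multiparous replicate 1, and in 8 other fits) to 55 (without virgin replicate 7) genes, with 33 without virgin 5, 24 without multiparous 3, 23 without virgin 1 and 5 without virgin 2. For MP against P the range was 3 to 197 (without multiparous replicate 5), with 3 without replicate 1 or 7 and 7 without replicate 2 or 3.

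Of the lists, 0 passed with an estimated correlation, 0 by fry directional, 0 by fry mixed and 0 without virgin 1 with an estimated correlation. Leaving out 1 library gave 13 to 25. P-coded libraries alone gave 14 lists (4 higher, 10 lower), with 9 of the 16 among them, and MP-coded alone 22 (15 higher, 7 lower), with 12 of the 16. The mesothelial list turned lower with P-coded libraries alone (adjusted p 0.844).

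Several log2 fold changes reversed, and the cause was not tested. Fits with tissue covariates cannot fully tell parity from the kidney sum, which was itself lower in multiparous hearts. With the kidney covariate the reversed values were Mzb1 0.076, Iglc2 2.66, Aurkb 0.38, Ccnb2 0.39, Kif11 0.27, Postn 0.067 and Pdk4 −0.0043. With kidney, liver and brain covariates they were Plvap −0.0095, Tmem108 −0.26, Cgnl1 −0.0028, Atf3 0.013, Mzb1 0.28, Iglc2 2.52, Aurkb 0.49, Ccnb2 0.63 and Kif11 0.39. Iglc2 was 1.27 with DESeq2 and 1.27 without its low-count filter, 0.51 with voom, 0.88 with quality weights and 0.50 with the block. With P-coded libraries alone, Gpm6a was −0.033, Myh6 0.011, Col3a1 0.024 and Atp2a2 0.020, and with total counts Myh6 was 0.013 and Atp2a2 0.027. Leaving out 1 library gave Iglc2 −1.39 to 1.30, Myh6 −0.052 to 0.0060, Myh7 −0.052 to 0.26, Atp2a2 −0.035 to 0.012 and Pdk4 −0.057 to 0.17.

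Removing mitochondrially encoded genes and using their share as a covariate were planned and not run, since they had no counts.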

Other observations

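The genes in this part were chosen after their values were seen. No member of these lists passed over all genes, and the lists did not pass the preset-correlation test. Adjusted over the list alone, 2 members of the sex and pregnancy hormone list passed: Greb1, an oestrogen-induced gene (log2 fold change 0.51, p 0.0318), and Hsd17b11, a steroid dehydrogenase (0.19, p 0.0122), while the receptor Esr1 did not. In the angiogenesis list the growth factor Fgf2 passed as higher (0.28, p 0.017) and Vegfa as lower (−0.21, p 0.0429). In the calcification list Runx2, an osteogenic factor (0.34, p 0.00336), and Apoa2 (2.71, p 0.00399) were higher and Spp1 lower (−3.36, p 0.00269). Spp1 was highest in virgin 1 and 3 (20.7 and 6.09 CPM), the libraries with the highest kidney sums (181 and 178 CPM), and Apoa2 is in the list of 12 liver genes. Cdh19, of Schwann cells, was higher in the nerve list (0.30, p 0.0104), as was Dbh (0.66, p 0.0476), while 9 of its 14 members lay lower (median −0.05).

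Transcripts of other tissues appeared in several libraries. Liver genes summed to 72.3, 325, 293 and 35.6 CPM in multiparous 1, 2, 7 and 8 and to 25.5 CPM in virgin 1, with albumin (Alb) alone at 234 CPM in multiparous 2. Neither liver nor brain sums differed past the threshold between the groups (exact permutation p = 0.134 and 0.674). Brain genes summed to 1.36 to 12.7 CPM in the 4 MP-coded libraries, to at most 0.176 CPM in the 4 P-coded ones (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0714), and to 5.13 and 3.95 CPM in virgin 7 and 8. Transthyretin (Ttr) measured 215.5 CPM in virgin 8 and the immunoglobulin light chain gene Igkc 170.6 CPM in virgin 1.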
